A study of Homo sapiens with 90 samples.

How the data were processed

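RNA-Seq was measured in MCF7, a breast cancer cell line, and in MCF7 carrying a short hairpin against p53 (p53sh). Cells were untreated (0 h) or received 10 Gy of gamma irradiation (IR). MCF7 after IR was sampled hourly from 1 to 12 h and at 24 h, p53sh at 2, 3, 4, 5, 7, 9 and 10 h. A further set of MCF7 cultures received IR and 3 additions of Nutlin 3a, which blocks MDM2 from binding p53, and was sampled hourly from 3 to 12 h and at 24 h. Single libraries stand at 2.5 and 7.5 h after IR and at 7.5 h with Nutlin. The series holds 75 RNA-Seq libraries, and 15 further samples (p53 ChIP-Seq, H3K27ac ChIP-Seq and inputs) for which no processed file was given were not analysed here.

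The submitters' processing notes list TopHat2 2.1.0 and Cufflinks 2.1.1 with hg19, an aligner and a program that estimates expression, without the role of each. The deposited table covers 20821 genes and 91 ERCC spike-in transcripts and was taken to hold FPKM, the unit Cufflinks reports. Whether libraries were scaled to each other further is not stated. FPKM carries no read counts, so the sequencing depth of each library is not known and no interval from counting could be computed. The column total ranged from 491069 to 703401 FPKM (median 590614). Between 12991 and 16202 genes per library were above 0.

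The ERCC share of the column total differed between replicate numbers. It was 2.34 to 4.45% in libraries numbered 1 (n = 36, median 3.35%), 4.10 to 11.6% in libraries numbered 2 (n = 31, median 6.85%) and 3.17 to 3.41% in libraries numbered 3 (n = 4). These counts leave out 2 identical columns numbered 2 and 2 columns without a number, both described next. GAPDH ranged from 3053 to 5193 FPKM in libraries numbered 1 and from 798.4 to 3763 in libraries numbered 2. The first 3 principal components of the log2 values held 30.8, 24.2 and 8.23% of the variance. On the first, most libraries numbered 2 lay on the opposite side from most libraries numbered 1.

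The columns for MCF7 replicate 2 at 2 h and at 10 h after IR were identical in every value. The labels do not tell which time the column belongs to. Both were therefore left out, a departure from the design fixed beforehand, and 2 h and 10 h after IR kept 1 library each. The 2 columns for IR and Nutlin at 10 h share a header and were used without a replicate number. Untreated MCF7 had 5 libraries (1_1, 1_2, 2_1, 2_2 and 3), IR at 1, 4 and 5 h had 3 each, and all other tested groups had 2.

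The fit took 70 libraries in 33 groups, with 37 residual degrees of freedom. Values were log2(FPKM + 1) without further scaling, and 12228 genes with a mean of at least 1 FPKM over the fitted libraries were tested. Contrasts of group means were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). A gene was called where the p-value, adjusted per contrast by Benjamini and Hochberg, was below 0.05. The prose gives log2 changes ± standard error and FPKM levels as mean ± SD with n. The samples' labels do not say whether replicates are separate cultures, so p-values measure the spread between samples that may be technical replicates.

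The 9 comparisons were chosen before the data were examined. The IR response was the mean of 2, 3, 4, 5, 7, 9 and 10 h minus 0 h, in MCF7 and in p53sh, and the difference between the lines was p53sh minus MCF7. The knockdown comparison was untreated p53sh minus untreated MCF7. Nutlin was tested as IR with Nutlin minus IR at matched times, averaged over 3 to 12 h, and at 24 h alone. A pulsed gene had to pass in 2 contrasts with the same sign, 2 and 3 h minus 5 and 6 h, and 8 and 9 h minus 5 and 6 h. Late against early was the mean of 10, 11 and 12 h minus the mean of 2, 3 and 4 h. The dip at 5 and 6 h, taken below the mean of 3 h and of 8 and 9 h, was compared between IR alone and IR with Nutlin. The knockdown comparison, the p53sh response and the difference share control libraries.

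There were 21 gene lists, written before the data were examined. They were 6 lists of p53 targets, E2F-driven G1/S genes, G2/M genes, replication-dependent histones, immediate early genes, NF-kappaB targets, interferon-stimulated genes, estrogen receptor targets, unfolded protein response, heat shock, cholesterol synthesis, hypoxia, double-strand break repair, luminal genes, markers of other cell types and housekeeping genes. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Camera p-values given without mention of an estimated correlation are at the preset one. These can be many orders smaller than with the estimated correlation. With the estimated correlation 170 list tests stayed called or uncalled and 40 lost their call. Symbols missing from the table and genes below the expression minimum were dropped from a list.

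Genes were named by a rule written beforehand. It takes the 5 largest changes in each direction that were called and had the same sign in replicates 1 and 2, and 12 fixed genes (TP53, CDKN1A, MDM2, PPM1D, BTG2, GDF15, PLK2, SESN1, FAS, BAX, XPC and RPS27L). It adds up to 4 called members per described list, or up to 2 where none was called. Antisense genes such as SGOL1-AS1 cannot be told from their sense partner without strand information, close paralogs are uncertain, and FPKM of short RNA genes (MIR600, MIR3911, MIR6721) is unreliable.

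The procedure was tested on simulated data, made from each gene's mean and whole residual columns of the real libraries drawn at random, with changes added to 200 of the 12228 genes. For a true log2 change of 1, recovery was 71.6% for IR in MCF7, 40.3% for the knockdown, 53.7% for IR in p53sh, 19.4% for the difference between lines, 89.6% for Nutlin at 3 to 12 h, 35.8% for Nutlin at 24 h, 52.2% for pulses, 68.7% for late against early and 34.3% for the dip. False calls numbered 0 to 4, except for the dip with 123. Each comparison had a single draw, and residual columns were drawn without regard to replicate numbers. The 200 changed genes are also far fewer than the knockdown or Nutlin comparisons called. None of these figures need therefore hold for the real layout.

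Alternatives covered the pseudocount, the expression minimum, scaling (median-of-ratios, quantile, ERCC), a replicate block, the variance trend, the groups in the fit, the choice of untreated libraries, shifted peak times, the ERCC share as a covariate and leaving out libraries singly or in sets. Pictures were drawn with matplotlib 3.10.9 in Python 3.11.15.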

Results

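TP53, the gene targeted by the short hairpin, stood at 2.32 to 6.03 FPKM in the 16 p53sh libraries and at 17.7 to 78.5 FPKM in the 58 distinct MCF7 columns. Untreated MCF7 held 52.9 ± 11.9 FPKM (n = 5) and untreated p53sh 4.11 ± 0.68 (n = 2), a log2 change of -3.38 ± 0.20 (adjusted p = 5.86e-17, limma). IR did not change TP53 by the test in MCF7 (0.22 ± 0.13, adjusted p = 0.71) or in p53sh (0.09 ± 0.18, adjusted p = 1).

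After IR, MCF7 raised the known transcriptional targets of p53. Averaged over 2 to 10 h, CDKN1A, which encodes the cell cycle inhibitor p21, rose by 3.12 ± 0.21 on the log2 scale (adjusted p = 6.8e-14, limma) and the antiproliferative gene BTG2 by 2.80 ± 0.14 (adjusted p = 7.82e-18). The death receptor gene FAS rose by 2.66 ± 0.21, the decoy receptor gene TNFRSF10C by 2.38 ± 0.22 and FOSL1, an AP-1 component, by 2.23 ± 0.25. MDM2, the ubiquitin ligase of p53, rose by 1.52 ± 0.20 (adjusted p = 1.38e-06) and the phosphatase gene PPM1D by 0.97 ± 0.18 (adjusted p = 0.000887). The lowest changes were in mitotic and replication genes, with CENPA at -1.1 ± 0.15, CDCA7 at -0.97 ± 0.10, SGOL2 at -0.95 ± 0.24 and CENPE at -0.95 ± 0.22. The antisense gene SGOL1-AS1, also called lower, was 0 in 41 of the fitted libraries. SESN1 (1.96 ± 0.19), XPC (1.19 ± 0.09) and RPS27L (0.79 ± 0.13) rose as well. GDF15 (2.30 ± 0.73, adjusted p = 0.122), BAX (1.08 ± 0.42, adjusted p = 0.318) and PLK2 (0.10 ± 0.19, adjusted p = 0.911) did not pass.

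Over the 12228 tested genes the IR response of MCF7 held 149 higher and 50 lower genes, 50 and 2 of them at least 2-fold, and 3 were short RNA genes. Of these, 148 and 50 had the same sign in replicates 1 and 2 taken alone. Those libraries also made the calls, so such counts, here and for the other comparisons, are not separate support. Scaling to the ERCC transcripts shifted the median change of all genes to 0.12 and gave 28 higher and 1 lower. With only the groups of this comparison in the fit the counts were 76 and 12, with untreated 1_2 and 2_2 alone 73 and 6, and with a replicate block 264 and 155. The lower count was 27 without untreated 2_2 and 33 without untreated 2_1 or without untreated 1_2.

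**Figure D1:**
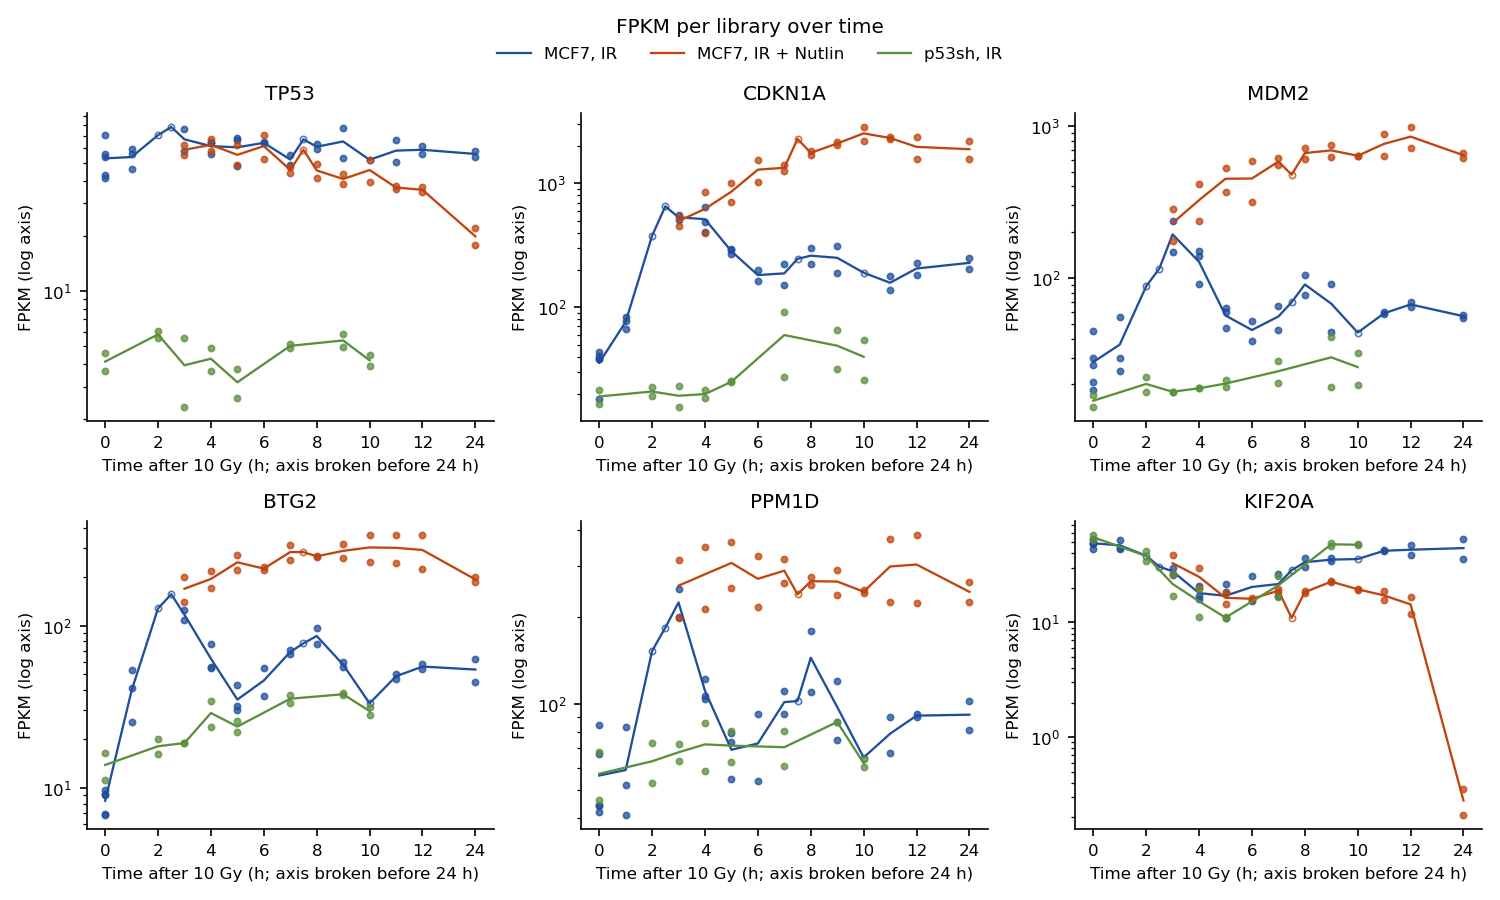
FPKM of TP53, CDKN1A, MDM2, BTG2, PPM1D and KIF20A in each library against time after 10 Gy, in MCF7 with IR, MCF7 with IR and Nutlin, and p53sh with IR. Points are libraries, lines join the group means, open points are times with 1 library, the FPKM axis is logarithmic and the time axis is broken before 24 h.

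All 6 lists of p53 targets rose in MCF7 after IR. Of 16 tested arrest and growth control genes 11 were higher and 0 lower (median log2 change 1.18, camera adjusted p = 4.33e-41), among them TP53INP1 (2.06 ± 0.21). Of 19 apoptosis genes 10 were higher (14 when adjusted over the list alone, median 1.05, adjusted p = 4.13e-30), including TNFRSF10B (1.18 ± 0.10) and TP53I3 (1.38 ± 0.33). Of 6 feedback genes 3 were higher (4 adjusted over the list alone, adjusted p = 8.47e-07), with CCNG1 at 0.93 ± 0.17. Of 10 repair and nucleotide supply genes 4 were higher (4 adjusted over the list alone, adjusted p = 1.02e-10), namely the damage recognition genes DDB2 (1.69 ± 0.13) and XPC, RRM2B (1.02 ± 0.24) and POLH (1.02 ± 0.14). Of 12 metabolism genes 4 were higher (5 adjusted over the list alone, adjusted p = 1.06e-10), with SPATA18 at 1.64 ± 0.17 and TIGAR at 1.04 ± 0.18. Of 37 membrane, secreted and other targets 12 were higher (19 adjusted over the list alone, adjusted p = 6.65e-30), with EDA2R at 1.85 ± 0.19 and HES2 at 1.62 ± 0.20.

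The cell cycle lists fell. Of 40 E2F-driven genes 8 were lower and 1 higher (17 and 1 when adjusted over the list alone, median -0.32, camera adjusted p = 2.46e-20), with MCM10 at -0.78 ± 0.16 and MCM6 at -0.70 ± 0.13. Of 43 G2/M genes 7 were lower (29 adjusted over the list alone, median -0.55, adjusted p = 3.53e-33), with AURKA at -0.94 ± 0.16 and the mitotic kinesin KIF20A at -0.87 ± 0.14. Heat shock genes fell as a list with 0 of 15 called (3 lower and 1 higher adjusted over the list alone, median -0.28, adjusted p = 0.000242), and cholesterol synthesis genes fell with 1 of 21 called, INSIG1 at -0.58 ± 0.16 (median -0.13, adjusted p = 0.000342). Interferon-stimulated genes rose as a list with 0 of 18 called (median 0.19, adjusted p = 0.0289).

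Several calls depended on the correlation within the list. Immediate early genes had 1 higher, FOSL1, and 1 lower of 25, MYC at -0.95 ± 0.26 (4 and 1 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.36 with an estimated correlation). NF-kappaB targets had 0 of 15 called (adjusted p = 0.032, adjusted p = 0.294 with an estimated correlation), hypoxia genes 0 of 18 (adjusted p = 0.032, adjusted p = 0.314 with an estimated correlation) and double-strand break repair genes 0 of 33 (adjusted p = 8.05e-05, adjusted p = 0.23 with an estimated correlation). Markers of other cell types had 3 tested members and 1 higher, ACTA2 at 1.38 ± 0.19 (adjusted p = 0.0121). Histones (0 of 24, adjusted p = 0.881), luminal genes (0 of 17, adjusted p = 0.881), housekeeping genes (0 of 24, adjusted p = 0.427) and unfolded protein response genes (2 higher of 20, DDIT4 at 1.73 ± 0.27 and SESN2 at 1.48 ± 0.26, adjusted p = 0.6) were not called. Estrogen receptor targets had 0 of 26 called, with a median of 0.06 but a test direction of down (adjusted p = 0.575).

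Time courses of the strongest targets had an early high point in MCF7. CDKN1A stood at 35.6 ± 10.1 FPKM untreated (n = 5), 532 ± 39.8 at 3 h (n = 2), 182 ± 25.2 at 6 h and 261 ± 54.1 at 8 h. MDM2 went through 28.1 ± 10.3, 194 ± 62.7, 45.6 ± 9.93 and 90.8 ± 19.2 FPKM at the same times. BTG2 stood at 8.35 ± 1.36 untreated, 117 ± 12.6 at 3 h, 35 ± 7.07 at 5 h (n = 3) and 86.3 ± 13.7 at 8 h, and PPM1D at 56.3 ± 18.5, 225 ± 35.5, 69.2 ± 12.7 and 144 ± 49.1. The fall from 2 and 3 h to 5 and 6 h was called for BTG2 (1.60 ± 0.21, adjusted p = 9.05e-06, limma), PPM1D (1.40 ± 0.26, adjusted p = 0.00233) and MDM2 (1.34 ± 0.29, adjusted p = 0.0125), but not for CDKN1A (0.98 ± 0.30, adjusted p = 0.195). In this fit, which has no replicate block, the second rise, 8 and 9 h over 5 and 6 h, did not pass for BTG2 (0.82 ± 0.18, adjusted p = 0.08), PPM1D (0.73 ± 0.23, adjusted p = 0.585), MDM2 (0.58 ± 0.26, adjusted p = 1) or CDKN1A (0.15 ± 0.27, adjusted p = 1). The 2 h group held only replicate 1, while 3, 5 and 6 h also held replicate 2, so replicate numbers were not balanced in the fall. BTG2, PPM1D, MDM2 and CDKN1A each stood higher at 8 h than at 6 h in replicate 1 and in replicate 2. These 2 hours were picked after the values were seen and not tested alone. The lack of a call does not show that these genes did not rise again.

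In the fit without a replicate block, the only gene that met both conditions of a pulse was KIF20A (0.82 ± 0.20, adjusted p = 0.0388, and 0.89 ± 0.18, adjusted p = 0.0197, limma). It stood at 48.9 ± 3.55 FPKM untreated, 17.1 ± 5.45 at 5 h and 42.1 ± 0.82 at 11 h. KIF20A thus fell from its untreated level and returned. In p53sh it took the same course, with 52.57 and 57.7 FPKM untreated, 11.13 and 10.9 at 5 h and 46.53 and 49.25 at 9 h. No gene was called with the mirror image, while 19 genes met the pulse condition and 28 the mirror image at unadjusted p below 0.05. The count of pulsed genes was 5 with a replicate block, 6 with the ERCC share as a covariate and 2 without libraries numbered 2. It was 0 with shifted peaks, a pseudocount of 0.1, quantile normalization, ERCC scaling, only the comparison's groups in the fit, or without libraries numbered 3, libraries above a 9% ERCC share or any of several single libraries.

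Among lists, the second rise was called for arrest genes (0 of 16, 3 adjusted over the list alone, median 0.27, camera adjusted p = 8.47e-06), metabolism targets (0 of 12, adjusted p = 0.023) and G2/M genes (2 higher of 43, 10 adjusted over the list alone, median 0.50, adjusted p = 3.81e-33). E2F-driven genes went the other way, 3 lower of 40 (16 adjusted over the list alone, median -0.47, adjusted p = 5.59e-31). Feedback genes had 0 of 6 called for the rise (1 adjusted over the list alone, adjusted p = 0.00138, adjusted p = 0.254 with an estimated correlation). For the first fall the arrest list had 2 members called in each direction of 16 (6 and 3 adjusted over the list alone, adjusted p = 0.027, adjusted p = 0.105 with an estimated correlation).

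Late after IR, G2/M genes returned while replication genes declined further. At 10 to 12 h against 2 to 4 h, CENPE was higher by 1.89 ± 0.27 (limma adjusted p = 8.82e-06), CENPA by 1.64 ± 0.18 and SGOL2 by 1.76 ± 0.30, together with ANXA1 (2.00 ± 0.29) and the smooth muscle actin gene ACTA2 (1.86 ± 0.23). E2F7 changed by -1.67 ± 0.19, the uracil glycosylase gene UNG by -1.62 ± 0.14, E2F1 by -1.56 ± 0.36, WDR76 by -1.56 ± 0.18 and FOSL1 by -1.67 ± 0.30. Of 43 G2/M genes 18 were higher (26 and 1 lower adjusted over the list alone, median 0.66, camera adjusted p = 1.34e-19), and of 40 E2F-driven genes 27 were lower (32 adjusted over the list alone, median -0.93, adjusted p = 3.54e-42). The p53 targets CDKN1A (-1.35 ± 0.26), MDM2 (-1.18 ± 0.25), BTG2 (-1.1 ± 0.17), PPM1D (adjusted p = 0.00401), SESN1 (-0.88 ± 0.23) and XPC (-0.75 ± 0.10) were lower late, and RPS27L (0.96 ± 0.16) was higher. TP53 (-0.24 ± 0.16, adjusted p = 0.5), FAS (-0.63 ± 0.26, adjusted p = 0.166), GDF15 (adjusted p = 0.704), PLK2 (adjusted p = 0.699) and BAX (adjusted p = 0.855) did not pass.

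The arrest list was split, 3 higher and 6 lower of 16 (3 and 6 adjusted over the list alone, adjusted p = 0.046, adjusted p = 0.119 with an estimated correlation), with CCNG2 at 1.26 ± 0.17 and GADD45A at -1.34 ± 0.20. Repair targets had 3 lower of 10 (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.0304), including PCNA at -1.09 ± 0.13, and cholesterol synthesis genes 1 lower of 21, TMEM97 at -0.56 ± 0.17 (median -0.35, adjusted p = 0.000785). In all, limma called 294 genes higher and 345 lower, of which 290 and 340 kept their sign in replicates 1 and 2 alone. A replicate block gave 1367 called genes, which included all 639 of these. Without the first library at 12 h (replicate 1) the counts were 184 and 218, and ERCC scaling gave 6 and 6.

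**Figure D2:**
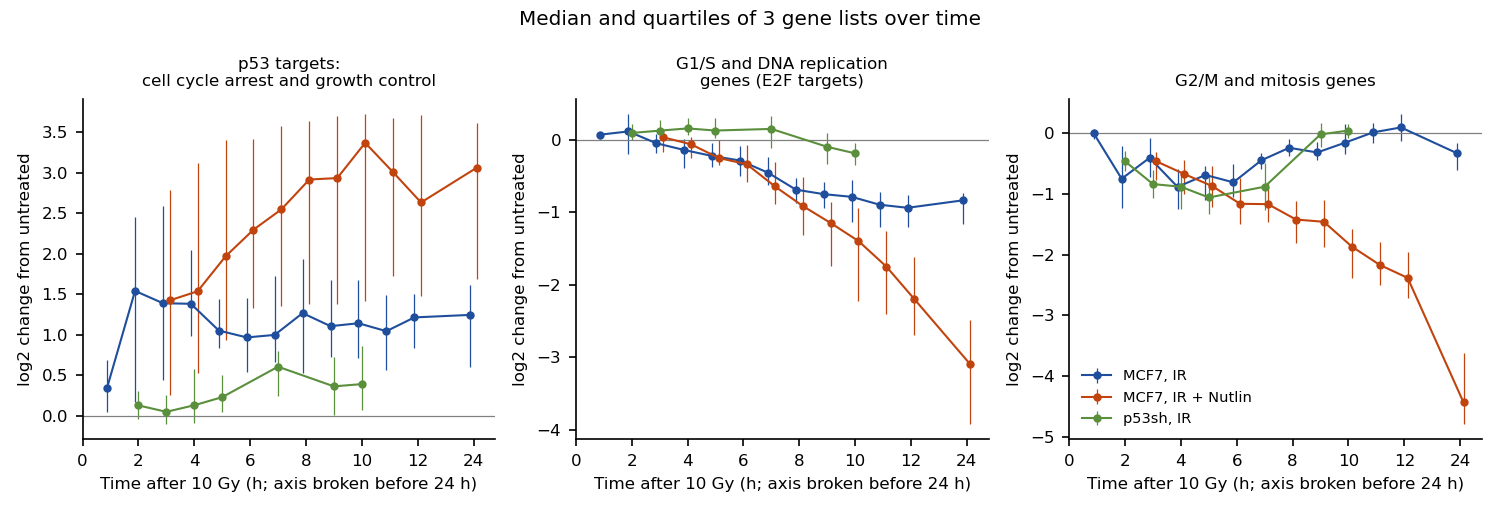
Median log2 change from the untreated libraries of the same line for the arrest, E2F-driven and G2/M lists against time after 10 Gy. Points are medians over the tested members of a list, bars run from the lower to the upper quartile of the members, and the time axis is broken before 24 h.

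Untreated p53sh differed from untreated MCF7 in many genes besides TP53. The collagen gene COL3A1 stood at 0.239 FPKM in MCF7 (n = 5) and 175 ± 39.6 in p53sh (n = 2), a log2 change of 7.14 ± 0.18 (adjusted p = 2.14e-29, limma). CLEC3A (7.31 ± 0.15), SGCG (4.67 ± 0.16) and SLC6A14 (4.58 ± 0.13) were also higher. The carbonic anhydrase gene CA2 stood at 302 ± 43.5 FPKM in MCF7 and at 0 and 0.33 in p53sh, and the lactate dehydrogenase gene LDHB at 234 ± 64.6 and at 0 in both p53sh libraries. The glycogen phosphorylase gene PYGL (-6.31 ± 0.25), the imprinted RNA H19 (-6.26 ± 0.73) and the actin-bundling gene PLS3 (-5.56 ± 0.38) were lower. MIR600, 0 in every untreated MCF7 library, was called higher.

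Among p53 targets BTG2 was higher in p53sh (0.66 ± 0.22, adjusted p = 0.0345, limma). CDKN1A (-0.82 ± 0.34, adjusted p = 0.0869), MDM2 (-0.74 ± 0.32, adjusted p = 0.104), GDF15 (-2.91 ± 1.15, adjusted p = 0.0747) and FAS (-0.48 ± 0.33, adjusted p = 0.387) did not pass. Of 19 apoptosis targets 6 were lower (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0546), including CYFIP2 (-2.27 ± 0.21) and TNFRSF10B (-1.07 ± 0.15). The only list called was immediate early genes, 6 lower of 25 (6 adjusted over the list alone, adjusted p = 0.0141, adjusted p = 0.671 with an estimated correlation), with KLF6 at -2.65 ± 0.23, EGR3 at -2.39 ± 0.40 and KLF4 at -2.27 ± 0.26. Estrogen receptor targets had 9 lower and 2 higher of 26 (9 and 3 adjusted over the list alone, adjusted p = 0.078), with PGR at -1.92 ± 0.36 and CXCL12 at 2.95 ± 0.36, and the receptor gene ESR1 stood at -1.02 ± 0.22.

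The knockdown comparison gave 1109 higher and 1068 lower genes in limma, 609 and 457 at least 2-fold, with 1104 and 1068 of the same sign in replicates 1 and 2 alone. Leaving out p53sh replicate 1 at 0 h gave 578 and 478, leaving out p53sh replicate 2 at 0 h gave 564 and 642, and ERCC scaling gave 225 and 180.

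In p53sh, G2/M genes fell as a list after IR. PIF1, a DNA helicase, fell by 1.72 ± 0.31 on the log2 scale (adjusted p = 0.0106, limma) and KIF20A fell by 1.1 ± 0.20 (adjusted p = 0.0106). CENPA fell by 1.04 ± 0.21 (adjusted p = 0.0299) and the mitotic cyclin gene CCNB1 by 0.94 ± 0.19 (adjusted p = 0.0309). KIF20A stood at 55.1 ± 3.63 FPKM untreated (n = 2), 11.0 ± 0.16 at 5 h and 47.9 ± 1.92 at 9 h. Of 43 G2/M genes 3 were lower (17 adjusted over the list alone, median -0.55, camera adjusted p = 7.46e-50), and of 40 E2F-driven genes 0 were called (median 0.06, adjusted p = 0.307). The arrest list rose with 0 of 16 called (1 adjusted over the list alone, median 0.32, adjusted p = 1.64e-05, adjusted p = 0.00148 without replicate 1 at 7, 9 and 10 h, where CDKN1A stood above replicate 2). BTG2 (0.91 ± 0.20, adjusted p = 0.118), CDKN1A (0.59 ± 0.30, adjusted p = 1), MDM2 (0.46 ± 0.29, adjusted p = 1) and FAS (0.50 ± 0.30, adjusted p = 1) did not pass.

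Apoptosis targets had 0 of 19 called in p53sh (1 adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.172 without those 3 libraries). The housekeeping control list was lower with 0 of 24 called (median -0.07, adjusted p = 0.0302, adjusted p = 0.291 with an estimated correlation). NF-kappaB targets (0 of 15 called, adjusted p = 0.0344, adjusted p = 0.335 with an estimated correlation) and heat shock genes (0 of 15 called, adjusted p = 0.032, adjusted p = 0.14 with an estimated correlation) lost their call in the same way. The p53sh response had 0 higher and 5 lower genes in limma, including the short RNA gene MIR6721, against 182 and 122 genes at unadjusted p below 0.05. Of the 5, 4 had the same sign in both replicates alone. A replicate block gave 11 called genes, 4 of them higher, and these 11 included all 5. Leaving out p53sh replicate 1 at 7, 9 and 10 h, an alternative added after the values were seen, gave 2 higher and 5 lower. With only the groups of this comparison in the fit 0 were lower, and leaving out 1 untreated p53sh library at a time (replicate 1 or replicate 2 at 0 h) gave 2 lower. PIF1, KIF20A, CENPA and CCNB1 kept their calls without replicate 1 at 7, 9 and 10 h. They lost them with only this comparison's groups in the fit and with either untreated p53sh library left out.

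Those 3 libraries held transcripts that untreated p53sh lacked or nearly lacked. LDHB stood at 5.36, 5.22 and 2.67 FPKM at 7, 9 and 10 h in replicate 1 and at 0, 1.16 and 0 in replicate 2, and CDKN1A at 91.9, 66 and 54 against 27.3, 31.8 and 25.7. Across 14 genes at least 16-fold lower in untreated p53sh, picked after the values were seen, the median level in these 3 libraries was 3.49, 3.21 and 2.17% of that in MCF7 with IR and Nutlin at 7 h. In the other p53sh libraries it ranged from 0.21 to 0.815%.

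**Figure D3:**
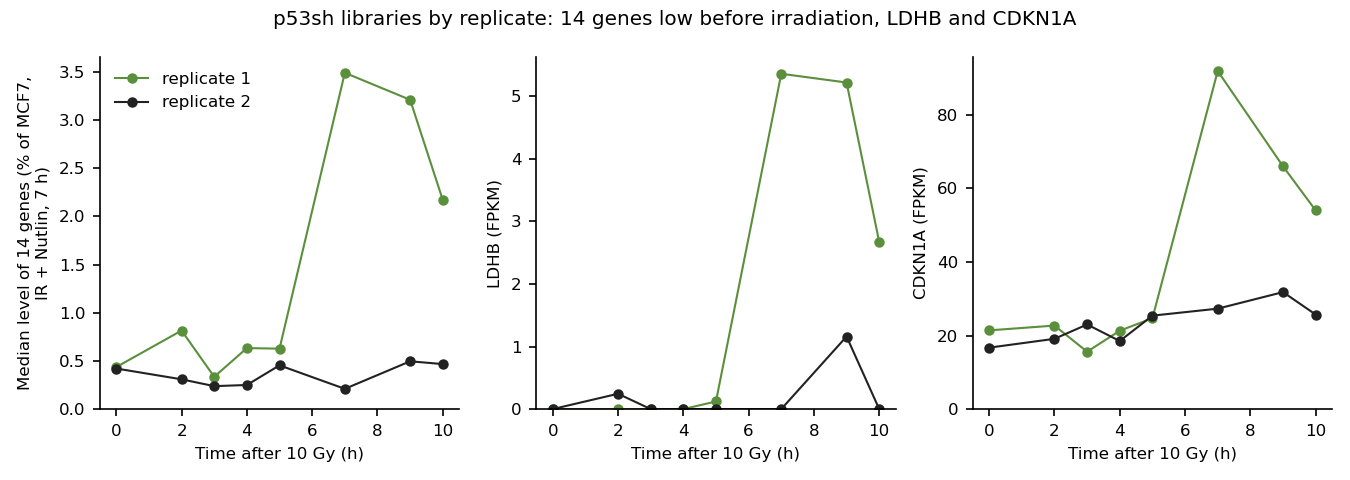
Levels in the p53sh libraries against time after 10 Gy, by replicate number. The panels give the median over 14 genes that were low in untreated p53sh, as a percent of their level in MCF7 with IR and Nutlin at 7 h, and FPKM of LDHB and CDKN1A. Each point is 1 library.

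The IR response of p53 targets was smaller in p53sh than in MCF7. The difference was -2.53 ± 0.37 for CDKN1A (adjusted p = 0.000139, limma), -2.16 ± 0.37 for FAS (adjusted p = 0.00141), -2.05 ± 0.37 for TNFRSF10C, -1.89 ± 0.25 for BTG2 (adjusted p = 1.73e-05), -1.87 ± 0.43 for FOSL1 and -1.66 ± 0.28 for GADD45A. DDB2 (-1.08 ± 0.22), XPC (-0.83 ± 0.15), SPATA18 (-1.45 ± 0.29) and EDA2R (-1.62 ± 0.34) differed too. The difference was positive for CDCA7 (0.86 ± 0.18, adjusted p = 0.0164), which fell in MCF7 and stood at -0.10 ± 0.15 in p53sh (adjusted p = 1). It was also positive for the clock gene PER3 (0.75 ± 0.17, adjusted p = 0.0484), at -0.26 ± 0.10 in MCF7 (adjusted p = 0.316) and 0.50 ± 0.14 in p53sh (adjusted p = 0.501). MDM2 (-1.05 ± 0.35, adjusted p = 0.91), PPM1D (-0.66 ± 0.32, adjusted p = 1), SESN1 (-1.33 ± 0.33, adjusted p = 0.0979) and RPS27L (-0.80 ± 0.22, adjusted p = 0.264) did not pass.

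All p53 target lists had lower values for the difference. Called members were 3 of 16 for arrest (8 adjusted over the list alone, median -1.03, camera adjusted p = 4.77e-29), 2 of 19 for apoptosis (6, adjusted p = 3.2e-21), 2 of 10 for repair (4, adjusted p = 1.43e-08), 1 of 12 for metabolism (4, adjusted p = 1.43e-08) and 3 of 37 for membrane, secreted and other targets (6, adjusted p = 5.72e-20). For feedback genes 0 of 6 were called (2 adjusted over the list alone, adjusted p = 2.19e-05, adjusted p = 0.0873 with an estimated correlation). E2F-driven genes were higher for the difference with 0 of 40 called (3 adjusted over the list alone, median 0.38, adjusted p = 1.93e-20). The G2/M list did not differ by the test (0 of 43 called, median -0.07, adjusted p = 0.378). The housekeeping list, a control, was lower with 0 of 24 called (median -0.15, adjusted p = 0.00669, adjusted p = 0.194 with an estimated correlation). Hypoxia genes (0 of 18 called, adjusted p = 0.0256, adjusted p = 0.31 with an estimated correlation) and double-strand break repair genes (0 of 33 called, adjusted p = 0.00287, adjusted p = 0.367 with an estimated correlation) also lost their call that way. In all the signed difference was higher for 2 genes and lower for 21 in limma, with 2 and 19 of the same sign in both replicates alone. Leaving out p53sh replicate 1 at 0 h gave 7 lower, and ERCC scaling gave 0 and 2, with 1 of these 2 among the 23 called in the unscaled values.

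Nutlin with IR raised p53 targets far above IR alone. Averaged over 3 to 12 h, SERPINB5 was higher by 3.29 ± 0.17, NUPR1 by 2.90 ± 0.18, MDM2 by 2.85 ± 0.12 (adjusted p = 1.81e-21, limma), TP53I3 by 2.61 ± 0.20 and CDKN1A by 2.40 ± 0.13 (adjusted p = 1.47e-18). CDKN1A stood at 496 ± 60.5 FPKM at 3 h (n = 2) and 2535 ± 450 at 10 h, and MDM2 at 230 ± 76.2 at 3 h and 850 ± 189 at 12 h. The mitotic kinase gene PLK1 changed by -2.25 ± 0.13 (adjusted p = 9.35e-18), CENPA by -1.83 ± 0.09, HMMR by -1.75 ± 0.16, PSRC1 by -1.64 ± 0.13 and UBE2C by -1.58 ± 0.08. TP53 itself was lower (-0.32 ± 0.08, adjusted p = 0.00186). BTG2 (2.12 ± 0.09), FAS (1.94 ± 0.13), GDF15 (1.72 ± 0.44), SESN1 (1.62 ± 0.11), PPM1D (1.49 ± 0.11), XPC (1.1 ± 0.05) and RPS27L (0.44 ± 0.08) were higher. BAX (0.50 ± 0.25, adjusted p = 0.198) and PLK2 (0.22 ± 0.11, adjusted p = 0.218) did not pass.

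Higher members were 11 of 16 for arrest (13 adjusted over the list alone, median 1.31, camera adjusted p = 1.07e-21), 14 of 19 for apoptosis (16, median 1.02, adjusted p = 1.46e-23) and 29 of 37 for membrane, secreted and other targets (30, median 0.95, adjusted p = 1.6e-39). They were 4 of 6 for feedback (4, adjusted p = 7.57e-09), 6 of 10 for repair with 1 lower (6 and 1, adjusted p = 2.66e-07) and 6 of 12 for metabolism (7, adjusted p = 3.08e-07). NF-kappaB targets rose, 9 of 15 (10 adjusted over the list alone, median 0.48, adjusted p = 6.68e-08), with TNFAIP3 at 1.16 ± 0.06 and NFKBIA at 0.78 ± 0.09. Immediate early genes had 14 higher and 1 lower of 25 (16 and 1 adjusted over the list alone, adjusted p = 1.49e-08, adjusted p = 0.124 with an estimated correlation), with ATF3 at 2.04 ± 0.11 and MYC at -1.30 ± 0.15.

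Cell cycle genes fell with Nutlin. G2/M genes had 42 lower of 43 (42 adjusted over the list alone, median -1.02, camera adjusted p = 6.12e-51) and E2F-driven genes 25 lower and 2 higher of 40 (30 and 2, median -0.38, adjusted p = 1.47e-10), with CCNA2 at -1.28 ± 0.11 and PCNA at 0.78 ± 0.06. Estrogen receptor targets had 7 lower and 1 higher of 26 (8 and 2 adjusted over the list alone, median -0.10, adjusted p = 0.00532), among them MYB at -0.96 ± 0.10. Double-strand break repair genes had 9 lower and 2 higher of 33 (10 and 2 adjusted over the list alone, adjusted p = 0.0108, adjusted p = 0.492 with an estimated correlation). In all limma called 1160 higher and 1006 lower genes, of which 1160 and 1003 kept their sign in both replicates alone. ERCC scaling moved the median change of all genes to -0.24 and gave 256 higher and 581 lower. There was no library with Nutlin and without IR. Untreated libraries numbered _1 are listed ahead of the IR series and those numbered _2 ahead of the Nutlin series, without a stated meaning. If these were separate experiments, their difference could not be told from that of Nutlin. Subtracting the difference between untreated libraries numbered _2 and _1 gave 133 and 41, and kept 166 of the 2166 calls. It rests on 2 untreated libraries per side, 2_1 among them, and adds their spread to the contrast.

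**Figure D4:**
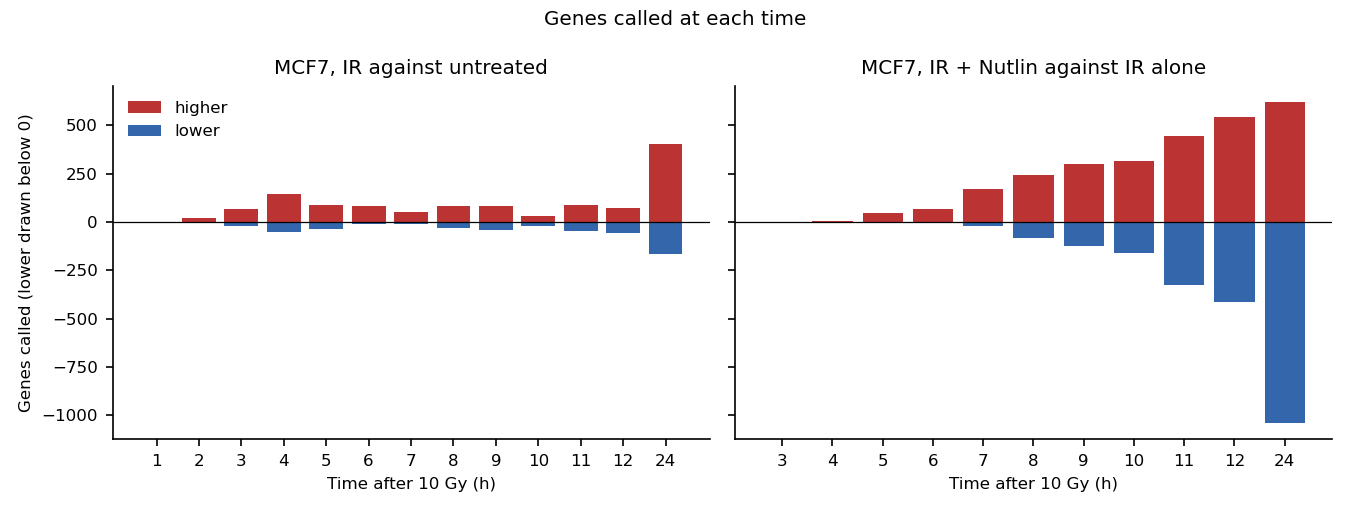
Number of genes called higher (above 0) and lower (drawn below 0) at each time, for IR against untreated MCF7 and for IR with Nutlin against IR alone. Each bar is a limma contrast at 1 time, at an adjusted p below 0.05.

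The difference made by Nutlin grew with time. At 3 h 1 gene was higher and 0 lower, at 6 h 69 and 3, at 9 h 300 and 126 and at 12 h 544 and 411 (limma). The median of the arrest list was 1.42 over untreated at 3 h, 3.37 at 10 h and 3.06 at 24 h with Nutlin. With IR alone it was 1.54 at 2 h, 0.97 at 6 h, 1.27 at 8 h and 1.24 at 24 h.

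The dip at 5 and 6 h was called deeper with IR alone than with Nutlin for 2 genes, BTG2 (1.30 ± 0.24, adjusted p = 0.0273, limma) and FAM212B (1.01 ± 0.17, adjusted p = 0.00656). Chance was not excluded for this count, since 8 of 100 splits of the libraries gave as many. With Nutlin BTG2 stood at 169 ± 41.9 FPKM at 3 h (n = 2) and 303 ± 79.9 at 10 h. MDM2 (1.40 ± 0.35, adjusted p = 0.237), PPM1D (1.34 ± 0.31, adjusted p = 0.204) and CDKN1A (0.77 ± 0.36, adjusted p = 1) did not pass. The arrest list differed with 1 of 16 called (3 adjusted over the list alone, median 0.63, camera adjusted p = 8.74e-08), as did feedback genes with 0 of 6 (3, median 0.51, adjusted p = 8.74e-08), apoptosis genes with 0 of 19 (3, adjusted p = 0.000339) and G2/M genes with 0 of 43 (0, median 0.37, adjusted p = 2.62e-12). The counts were 2 deeper with IR alone and 0 deeper with Nutlin, against 148 and 170 at unadjusted p below 0.05. Quantile normalization, ERCC scaling, the identical columns kept and only the comparison's groups in the fit each gave 0 deeper with IR alone. A replicate block gave 7. In the simulated data, drawn without regard to replicate numbers, this contrast gave 123 false calls, which need not hold for the real layout.

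At 24 h, G2/M genes were far lower with Nutlin and IR than with IR alone. UBE2C stood at 3.08 ± 1.98 FPKM against 304 ± 15.9 with IR alone (n = 2 each), a log2 change of -6.31 ± 0.24 (adjusted p = 2.16e-22, limma), and KIF20A at 0.281 ± 0.101 (-5.12 ± 0.26). CDC20 (-5.24 ± 0.45), KIF2C (-5.23 ± 0.21) and PRR11 (-5.10 ± 0.26) were lower as well. The aldo-keto reductase gene AKR1B10 (4.83 ± 0.28), TP53I3 (4.59 ± 0.61), the aldehyde dehydrogenase gene ALDH1A3 (4.06 ± 0.46) and NUPR1 (3.65 ± 0.56) were higher, and MIR3911, 0 in both libraries with IR alone, was called higher. TP53 stood at 19.9 ± 3.01 FPKM with Nutlin and 55.9 ± 3.38 without (-1.46 ± 0.24, adjusted p = 1.35e-05). CDKN1A (3.03 ± 0.40), MDM2 (3.49 ± 0.38), FAS (2.70 ± 0.40), BTG2 (1.84 ± 0.27) and PPM1D (1.41 ± 0.34) were higher. GDF15 (3.51 ± 1.37, adjusted p = 0.0885) and BAX (1.24 ± 0.79, adjusted p = 0.375) did not pass.

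G2/M genes had 40 lower of 43 at 24 h (41 adjusted over the list alone, median -3.86, camera adjusted p = 7.23e-81) and E2F-driven genes 35 of 40 (35, median -2.12, adjusted p = 7.36e-44), with CCNA2 at -4.85 ± 0.34 and RRM2 at -3.54 ± 0.32. Arrest targets had 12 higher of 16 (12, median 1.65, adjusted p = 1.52e-11) and apoptosis targets 11 of 19 (11, adjusted p = 1.52e-11). Estrogen receptor targets had 12 lower and 1 higher of 26 (12 and 1, median -0.62, adjusted p = 0.000737), with PGR at -2.23 ± 0.43. Double-strand break repair genes had 13 lower and 1 higher of 33 (15 and 1, adjusted p = 2.49e-10, adjusted p = 0.055 with an estimated correlation), with RAD51 at -3.21 ± 0.21. Limma called 621 genes higher and 1039 lower, of which 620 and 1036 kept their sign in both replicates alone. Without replicate 2 at 24 h with IR alone 497 were lower, without Nutlin replicate 1 at 24 h 528 were lower, without Nutlin replicate 2 at 24 h 390 were higher. ERCC scaling gave 89 and 208. Subtracting the difference between untreated libraries numbered _2 and _1 gave 273 and 460, only the comparison's groups in the fit gave 52 and 135, and a replicate block gave 1115 and 1606.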

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

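The patterns weighed here were chosen after the values had been seen. The criteria for the 2 mixing tests, the basal target test and the untreated library test were written before those tests were run, and the TP53 ratio, the ERCC covariate test and all splits were chosen after.

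CDKN1A at 7 h in p53sh stood at 91.9 FPKM in replicate 1 and 27.3 in replicate 2. Material from unmodified MCF7 taken 7 h after IR would have to make up 34.4% of the library to give this excess. Yet 14 genes at least 16-fold lower in untreated p53sh exceeded replicate 2 by a median of only 2.62% of their level in that source. This argues against MCF7 at 7 h after IR. Other times were not tried, and CDKN1A stood at 652.9 FPKM in MCF7 at 2.5 h, so IR material from another time was not excluded. Material from MCF7 given IR and Nutlin, at 7 h, would have to make up 4.83%, and the same genes exceeded replicate 2 by a median of 3.18% (quartiles 2.34 to 4.93). A small admixture of that source could account for the CDKN1A excess. Other p53 targets were mixed at 7 h. TP53I3 (22.5 against 9.08 FPKM), GDF15 (33 against 1.96) and SERPINB5 (1.71 against 0) were also higher in replicate 1. MDM2 stood at 28.58 against 20.31, with 554.7 and 612 in that source, and BTG2 at 37.29 against 33.59. PPM1D was lower in replicate 1 (60.63 against 80.57). At 9 and 10 h MDM2 stood at 40.9 and 32.1 in replicate 1 against 19.3 and 19.9 in replicate 2. SERPINB5 stood at 2.69 and 2.24 against 0 at both times. BTG2 (38.39 and 28.12 against 37.13 and 31.38) and PPM1D (86.09 and 64.12 against 86.62 and 60.18) differed little at those times. The admixture is left open. The TP53 ratio of replicate 1 to replicate 2 was 1.06, inside the 0.42 to 1.44 of the other 7 times, which does not favor a weaker knockdown. A check of line-specific sequence variants in the reads would test the admixture.

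Untreated p53sh and MCF7 differed in 2177 called genes. Of the genes lower in p53sh, 18.4% (197 of 1068) were called higher with Nutlin, against 9.49% of all tested genes, and 14% were called lower with Nutlin, against 8.23%. This fell short of the criterion written for loss of basal p53 target expression as the main source of the lower genes. The test cannot decide that question, since its comparator, IR alone, had already raised p53 targets. It also leaves out the 1109 genes higher in p53sh. Library quality as read from the ERCC share does not account for most of the 2177 calls, since all kept their direction with that share in the fit. Divergence of the lines in culture may be a cause, but no test of it was possible with these files, and an untreated line with a control hairpin would be needed.

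Untreated MCF7 replicate 2_1 stood apart from the other 4 untreated libraries. Its deviation followed, across 12228 genes, the slope of expression on the ERCC share in 63 libraries of other groups (Pearson r 0.869), so a difference in library quality could account for it. No biological explanation was tested.

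In other splits of the same libraries, drawn 100 times with the real one included, 4 gave as many called genes for IR in MCF7 (highest other 5069), 1 for Nutlin at 3 to 12 h (highest other 2132) and 1 for late against early (highest other 138). For pulsed genes 7 did (highest other 18) and for the dip 8 did (highest other 86), so in these splits chance is not excluded for the counts of 1 and 2. The IR split with 5069 genes set libraries with a mean ERCC share of 3.47% against 8.61%, so the splits also carry a structure of the samples.

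With libraries exchanged only within a replicate number, the highest other split had 89 genes for IR, 1098 for Nutlin and 82 for late against early, below the real 199, 2166 and 639. For pulsed genes 8 of 100 such splits gave as many as the real 1 (highest other 4), and for the dip 10 gave as many as the real 2 (highest other 313). With a replicate block in the fit the real counts were 5 and 7, and 3 of 100 splits gave as many pulsed genes (highest other 20) and 12 as many dip genes (highest other 593). What made the blocked split with 20 pulsed genes, several times the real count, so large was not tested, and the pulsed count is left open. The knockdown, p53sh, difference and 24 h comparisons have 2 libraries on at least 1 side, and splits were drawn only for comparisons with at least 3 on each.

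Dixon's ratio exceeded its critical value of 0.71 for 22 of 194 items in the 5 untreated MCF7 libraries, where about 5% would by chance. The 194 include MIR600 and MIR3911, which were 0 in all 5 libraries and had no ratio. In 20 of the 22 the extreme library was 2_1. The ratios were 0.783 for CDKN1A, 0.754 for PLK2, 0.741 for BAX, 0.721 for CCNA2, 0.878 for INSIG1, 0.806 for E2F2, 0.75 for STARD4, 0.752 for HMGCS1, 0.768 for FANCI, 0.836 for TFRC, 0.744 for PLK1, 0.715 for PCNA, 0.714 for SUSD6, 0.801 for SQLE, 0.837 for AKR1B10, 0.758 for CDC20, 0.824 for CTGF, 0.748 for HSPD1, 0.721 for RAD54L and 0.745 for E2F1. In PSAT1 (0.73) the extreme library was 2_2 and in FKBP4 (0.746) it was 1_1.

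The signed IR change was higher in p53sh than in MCF7 for 2 genes and lower for 21. The dip was deeper with IR alone by 1.30 for BTG2 and 1.01 for FAM212B on the log2 scale. CDKN1A stood at 652.9 FPKM in the single library at 2.5 h, 245.7 in that at 7.5 h, 2286 in that at 7.5 h with Nutlin and 136.4 in the column given for both 2 h and 10 h, against a highest untreated value of 43.46.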

How the results depend on the processing

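The alternatives with the ERCC transcripts (scaling, covariate, libraries above 9% left out), the identical columns kept, libraries numbered 2 left out and p53sh replicate 1 at 7, 9 and 10 h left out were chosen after the results had been seen, and the others before. Counts are given as higher and lower where both moved by over 1.5 times, and of 258 counts compared 141 stayed within that factor and 117 did not. The cause was not tested for any value that moved. Tests meant for read counts were not run, since the table holds FPKM.

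With a replicate block the counts were 264 and 155 for IR in MCF7, 1799 and 1768 for the knockdown, 4 higher for IR in p53sh, 5 and 34 for the difference, 1115 and 1606 for Nutlin at 24 h, 5 pulsed genes, 638 and 729 late against early and 7 for the dip. The labels do not say whether replicate numbers pair the libraries, but deviations from group means went with the numbers. The main fit has no term for the replicate number, so its spread includes that structure. The correlation of deviations from group means ran from -0.361 to 0.836 (median 0.525, 934 pairs) for the same number and from -0.81 to 0.611 (median -0.488, 1166 pairs) for different numbers, and 58 of 66 libraries correlated best with their own number.

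With the ERCC share as a covariate the counts were 274 and 119 (IR), 1912 and 1830 (knockdown), 4 and 8 (p53sh), 38 lower (difference), 1870 lower (Nutlin), 1260 and 1723 (Nutlin at 24 h), 6 pulsed and 1 mirror image, 765 and 853 (late) and 11 and 3 (dip). With ERCC scaling they were 28 and 1, 225 and 180, 1 lower, 0 and 2, 256 and 581, 89 and 208, 0 pulsed, 6 and 6, and 0, and the median of all genes moved to 0.12 for IR, -0.18 for the difference and -0.24 for Nutlin. Leaving out libraries above a 9% ERCC share gave 8 lower in p53sh, 1 higher for the difference, 0 pulsed and 9 and 3 for the dip.

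Leaving out libraries numbered 2 gave 29 and 9 for p53sh, 23 and 37 for the difference, 642 lower for Nutlin, 410 and 680 for Nutlin at 24 h, 2 pulsed and 7 mirror image, 152 higher late and 29 and 21 for the dip. Most groups then hold 1 library, so the spread in that fit comes from the few groups with more, and none of it from p53sh. Leaving out libraries numbered 3 gave 3 lower in p53sh, 0 higher for the difference, 0 pulsed and 1 for the dip. Keeping the identical columns gave 0 higher for the difference, 162 and 206 late and 0 for the dip. Without p53sh replicate 1 at 7, 9 and 10 h there were 2 higher in p53sh.

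With untreated libraries 1_1 and 2_1 only, the counts were 79 and 21 for IR and 0 and 13 for the difference. With 1_2 and 2_2 only they were 73 and 6 for IR, 707 lower for the knockdown and 0 and 10 for the difference. Subtracting the difference of the untreated libraries numbered _2 and _1 gave 133 and 41 for Nutlin and 273 and 460 at 24 h.

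With only the groups of a comparison in the fit the counts were 76 and 12 (IR), 413 and 386 (knockdown), 0 lower (p53sh), 1 higher (difference), 52 and 135 (Nutlin at 24 h), 0 pulsed, 28 and 37 (late) and 0 and 1 (dip). Without the filter they were 10 and 59 (p53sh), 4 and 66 (difference), 1031 higher (Nutlin at 24 h), 2 mirror image and 5 and 4 (dip). A pseudocount of 0.1 gave 1 and 3 (p53sh), 0 and 11 (difference) and 0 pulsed. Quantile normalization gave 31 lower (IR), 2 lower (p53sh), 1 higher (difference), 0 pulsed and 0 (dip). Median-of-ratios scaling gave 1 higher (difference), no intensity trend gave 1 deeper with Nutlin (dip), and shifted peaks gave 0 pulsed.

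Directions turned in 11 results that were called in the main fit or in the alternative. For Nutlin, IRF9 was -0.23 and INSIG1 0.11 after the untreated difference was subtracted, and KDM3A was -0.0255 with ERCC scaling. With shifted peaks the fall of FAS was 1.33 on the log2 scale, and the list tests for the fall gave adjusted p = 0.00159 (repair targets), 6.64e-06 (membrane targets) and 0.307 (G2/M genes), and 0.0235 for hypoxia genes in the second rise. Without libraries numbered 2 the second rise gave 0.0012 for immediate early genes and 0.0419 for hypoxia genes. Without the 3 p53sh libraries the histone list gave 0.0397 for the p53sh response.

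Leaving out 1 library at a time (65 fits) gave 113 to 163 higher and 27 to 66 lower for IR, 564 to 1114 and 478 to 1053 for the knockdown, 0 to 3 and 2 to 5 for p53sh, 0 to 5 and 7 to 24 for the difference, 1087 to 1241 and 920 to 1135 for Nutlin, 390 to 426 and 497 to 1013 at 24 h, 0 to 2 pulsed and 0 to 1 mirror image, 184 to 300 and 218 to 362 late, and 0 to 6 and 0 to 3 for the dip. For IR, 27 genes were lower without untreated 2_2 and 33 without untreated 2_1, without untreated 1_2 or without replicate 1 at 7 h. The knockdown gave 578 and 478 without p53sh replicate 1 at 0 h and 564 and 642 without replicate 2. For the difference 7 and 9 genes were lower without these. Nutlin at 24 h gave 497 lower without IR replicate 2, 528 lower without Nutlin replicate 1 and 390 higher without Nutlin replicate 2, and late against early gave 184 and 218 without replicate 1 at 12 h.

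For named genes, 5013 of 5844 values under the other alternatives kept their direction and stayed called or uncalled, 733 lost the call and 55 gained one. A further 39 changed sign without a call in either fit, and 4 changed sign with a call in at least 1 of the fits. The size of the change was not compared. On leaving out 1 library 6181 of 6617 were kept, 383 lost the call, 3 gained one and 50 changed sign without a call. For list tests 2813 of 3213 were kept, 187 lost the call, 60 gained one, 146 changed sign without a call and 7 changed sign with one. Of 806 counts at single times 335 moved by over 1.5 times under the other alternatives.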

Other observations

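The comparison described here, 9 and 10 h against 4 and 5 h after IR, was chosen after the time courses had been seen, as were all other values in this part. In p53sh, G2/M genes were higher as a list at the later times. KIF20A was higher by 1.82 ± 0.19 (adjusted p = 3.96e-08, limma), HMMR by 1.73 ± 0.36 (adjusted p = 0.0104), PLK1 by 1.72 ± 0.28 (adjusted p = 0.000614) and DLGAP5 by 1.71 ± 0.33 (adjusted p = 0.00458). Of 43 G2/M genes 15 were higher (39 adjusted over the list alone, median 1.02, camera adjusted p = 1.09e-81), and E2F-driven genes were lower as a list (median -0.33, adjusted p = 1.94e-11). With an estimated correlation camera gave adjusted p = 7.7e-08 for G2/M genes and 0.00466 for E2F-driven genes. Over all genes 38 were higher and 6 lower.

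The later side includes replicate 1 at 9 and 10 h, where genes low in untreated p53sh stood at 3.21 and 2.17% of their MCF7 level. Without replicate 1 at 7, 9 and 10 h, 8 of 43 G2/M genes were higher (34 adjusted over the list alone, median 0.99, camera adjusted p = 1.39e-57, adjusted p = 6.21e-06 with an estimated correlation). In that fit, which keeps only replicate 2 of p53sh at 9 and 10 h, KIF20A stood at 1.85 and PLK1 at 1.77. HMMR (1.62) and DLGAP5 (1.66) lost their calls, though their changes stayed about as large. E2F-driven genes had a median of -0.24 (adjusted p = 0.000195, adjusted p = 0.234 with an estimated correlation).

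In MCF7 over the same times 8 of the 43 G2/M genes were higher (20 adjusted over the list alone, median 0.63, camera adjusted p = 1.79e-35), with CENPE at 1.58 ± 0.31, CENPA at 1.31 ± 0.20 and AURKA at 1.19 ± 0.22, and E2F-driven genes had 9 lower (median -0.64, adjusted p = 4.13e-41). The estimated correlation gave camera adjusted p = 0.000151 for G2/M genes and 1.32e-07 for E2F-driven genes. The difference, p53sh minus MCF7, was 0.40 in the median for G2/M genes (adjusted p = 2.7e-09, adjusted p = 0.0719 with an estimated correlation) and 0.36 for E2F-driven genes (adjusted p = 6.28e-13, adjusted p = 0.00191 with an estimated correlation).

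The column given for both 2 h and 10 h held CDKN1A at 136.4 FPKM and BTG2 at 32.7. Across genes, its deviation from the mean of the MCF7 replicate 2 libraries after IR correlated with that of the library at 9 h with r 0.279, at 12 h with 0.192 and at 11 h with 0.164, and at 1, 3, 4, 5, 6, 7, 8 and 24 h with 0.0458, -0.113, 0.0157, -0.0836, -0.135, -0.152, -0.0841 and -0.0524. The column thus resembled the libraries around 10 h more than those at 1 and 3 h. All these correlations were low and rest on 1 column, so its time was not settled.

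The single libraries held BTG2 at 155.9 FPKM and MDM2 at 115.6 at 2.5 h, and at 77.7 and 69.3 at 7.5 h. With Nutlin at 7.5 h they stood at 283.3 and 478.5, and KIF20A at 10.9 against 28.5 with IR alone.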
